A study of Mus musculus with 9 samples.

How the data were processed

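Gene expression was measured in mouse lung on 9 single-colour Affymetrix GeneChips hybridised with biotin-labelled cRNA, 3 for each of 3 groups: control lungs and lungs taken 24 h or 48 h after exosome injection. Groups and replicate numbers were read from the labels, which call the samples biological replicates. The labels mention 3 mice at each time point and an experiment carried out in triplicate, without stating whether an array held RNA of 1 mouse or of a pool, so p-values measure the spread between these samples. What the control mice received is not given in the sources used here.

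Each deposited sample file lists 22690 probe sets with a signal intensity, a detection call and a detection p-value, per the file headers, in the layout of an Affymetrix expression analysis export. The authors scaled the linear signal intensity of every array: the mean with 2% of values trimmed at each end lay between 500.1 and 500.2 on all 9 arrays. The software version, the background method and the summary method are not given in the sources used here. The labels name a whole-genome mouse chip and a number of transcripts above the number of probe sets in the files, so the chip type stays uncertain, and the files were used as they stand. The deposited detection p-value was below 0.05 for exactly as many probe sets as carried a Present call. No other column of per-sample values was left unused (0 columns).

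The authors' table of processed intensities for the whole series was set against the sample files with a tolerance of 0.051 signal units. Its 9 columns each held the values of a file with another label: the columns labelled 24 h held the control files, those labelled 48 h held the 24 h files and those labelled control held the 48 h files. The match was complete for 8 columns. The remaining column differed at 273 probe sets, of which 272 matched after displacement by 1 row following an empty line in the source file. Column medians ran from 174 to 185 signal units and the scale was linear with no centring. Which groups a comparison sets against each other, and in which direction, therefore depends on which source carries the right labels. With the table's labels, 24 h against control compares the control files with the 48 h files. Its 48 h against control compares the 24 h files with the 48 h files, and its 48 h against 24 h the 24 h files with the control files. Names written inside the sample files (0 h, 24 h, 48 h) matched their groups in all 9 cases. The titles of the 48 h samples open with 24 hour and then state 48 hours, as their source names do, and 48 h was used. On these grounds the sample files gave the reported values and the table an alternative.

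The deposited signal had already been summarised, so no background step was repeated. Signals were raised by an offset of 16, taken to log2 and quantile normalised between arrays. The 64 control probe sets were left out. A probe set was tested if its detection p was below 0.05 on every array of at least 1 group, which kept 15886 probe sets for 9281 genes. Gene names came from the platform annotation with symbols of the assembly GRCm38.p6. Of all probe sets, 20393 had 1 gene symbol, 691 had several and were not named, and 1606 had none listed. Updating through Entrez identifiers changed 0 symbols. No genome was used. A fold change here is on the scale of the offset signal and understates changes of dim genes.

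Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single model of all 9 arrays with a mean for each group, at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were 24 h against control, 48 h against control, 48 h against 24 h, and the average of both times against control. Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, on 43 lists fixed before the data were examined: markers of lung, blood, muscle, fat and melanocyte cells, and pathway lists. Each gene entered by its tested probe set with the highest mean. The adjustment for lists ran over the 43 lists within a comparison. Alternative list tests were camera with an estimated correlation and fry, for which statmod 1.5.0 supplied the numerical integration.

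Named genes followed a rule fixed at the same stage. Where fewer than 10 probe sets passed, the 5 highest and 5 lowest genes by moderated t were taken and said not to pass. To these were added S100a8, S100a9, Tnf, Met, Kit, Fn1, Mmp9, Lox and Vegfa in every comparison, and up to 4 members with the smallest p from each list past its threshold. A gene's value is that of its tested probe set with the highest mean over the 9 arrays.

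Replicate numbers are shared between groups in the labels. Deviations from the group means correlated between 0.275 and 0.651 over the 9 pairs of arrays with the same number. Over the 18 pairs that differed in both number and group they correlated between -0.561 and 0.308. When matched only to arrays of the other groups, 9 of 9 arrays matched best with an array of their own number. The numbers were therefore treated as pairing the samples, and a fit with the replicate number as a block was run beside the fit without it. The files give no slide or scan batch.

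The procedure was tested on simulated data shaped like the 24 h against control comparison, with 15886 probe sets. Without the block, limma recovered 4 of 67 probe sets changed 1.5-fold, 45 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 0 false calls among unchanged probe sets. With the block it recovered 53 of 67, 65 of 67 and 66 of 66, with 13 false calls. In the simulation of lists, on 9206 genes with noise drawn independently for each, camera called 0 of 43 unchanged lists of 20 genes picked at random. Genes of the real lists can move together, so this does not show how often camera calls such lists falsely. The number of arrays limits the precision: the median standard error of a log2 difference was 0.15 without the block and 0.11 with it.

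Alternatives covered normalisation, offset, filter, source of values, model of the spread, array weights, the block, averaging of probe sets, list tests and leaving out each array in turn. Fits that left out an array kept the normalisation and the tested probe sets of all 9 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.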

Results

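Lungs of C57BL/6 mice were profiled after tail-vein injection of 10 µg of exosome protein from B16-F10, a mouse melanoma line that colonises the lung. Exosomes are small vesicles that cells release and that carry protein and RNA to other cells. Control lungs and lungs taken 24 h or 48 h after injection were each represented by 3 arrays. The comparisons ask which lung genes differ from control after exosomes reach the circulation, and whether the difference depends on the time since injection. Present calls covered 69.9% to 72.6% of probe sets, and median signals ran from 174 to 185 units. The first principal component held 41.9% of the variance and placed the 3 arrays numbered replicate 1 (scores -25.96 to -24.45) apart from the other 6 (4.67 to 18.04), whatever their group.

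**Figure D1:**
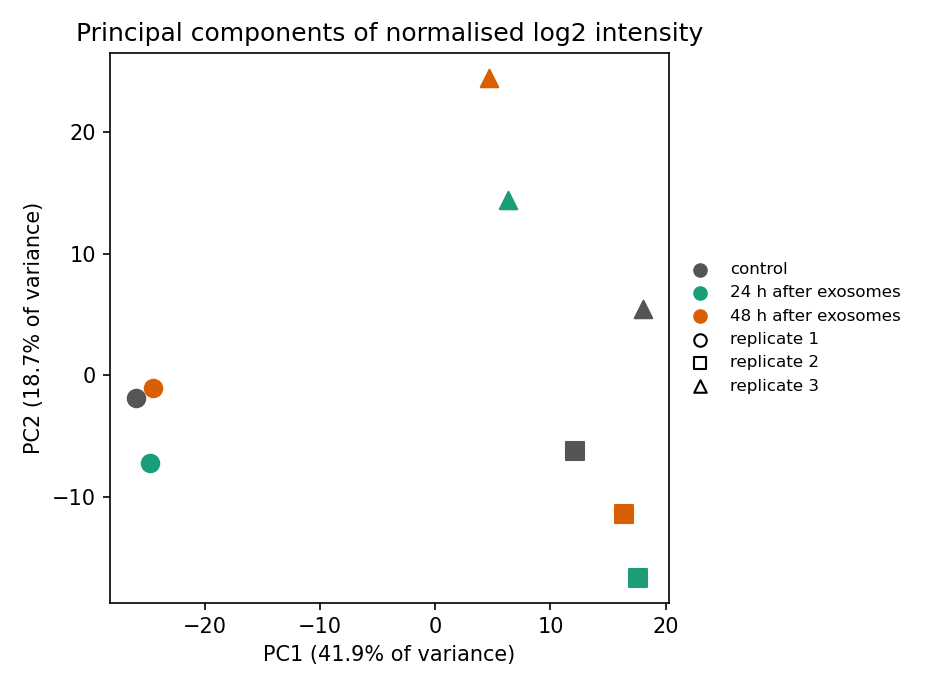
Scores of the 9 arrays on the first (41.9% of variance) and second (18.7%) principal components of normalised log2 intensity, coloured by group, with the marker shape giving the replicate number. Arrays cluster by replicate number, with the 3 replicate 1 arrays at PC1 scores of -25.96 to -24.45.

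At 24 h after exosomes, heart muscle genes fell as a group, while genes of adipocytes, of lipid and surfactant metabolism and of the mitochondrial respiratory chain rose, with camera's preset correlation. Each of these 4 calls ended with an estimated correlation (adjusted p = 0.964 with an estimated correlation), and no single gene passed the test. Groups and directions follow the labels of the sample files. With those of the authors' series table, whose columns carry other labels for the same values, each comparison sets other groups' files against each other. There camera's direction turned for 3 of these 4 lists, all but the lipid list. It turned for 8 of 9 lists at 48 h (not the cardiac list), for 7 of 9 between the times (not the B cell and immediate early lists) and for 6 of 6 in the average. Of 18 measured cardiac muscle genes, 16 were lower than control, with a median log2 change of -0.285 (adjusted p = 0.00202, and adjusted p = 0.964 with an estimated correlation). They included Myh6, the alpha cardiac myosin heavy chain, at 0.691-fold (95% CI 0.434 to 1.1), and Ryr2, the calcium release channel of heart muscle, at 0.783-fold (0.552 to 1.11). Mybpc3, a cardiac myosin-binding protein, was at 0.788-fold and Ttn, which encodes titin, at 0.75-fold. The cardiac call ended without 24 h replicate 2 (median -0.136, adjusted p = 0.36), control replicate 1 (-0.189, 0.241) or control replicate 2 (adjusted p = 0.091).

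Among adipocyte genes, 10 of 12 were higher at 24 h (median log2 0.185, adjusted p = 0.0355, and adjusted p = 0.964 with an estimated correlation). Thrsp, a regulator of fatty acid synthesis, stood at 2.1-fold (95% CI 1.14 to 3.86), the adipokine Retn at 1.35-fold and the carbonic anhydrase Car3 at 1.34-fold, whereas Slc2a4, the insulin-responsive glucose transporter, was at 0.802-fold. Of 21 lipid and surfactant genes, 16 were higher, with a small median of 0.038 (adjusted p = 0.0355, and adjusted p = 0.964 with an estimated correlation). The list did not pass with the replicate block (adjusted p = 0.0505). Srebf1, a transcription factor of lipid synthesis, was at 1.22-fold (1.01 to 1.48), Acaca, which makes malonyl-CoA, at 1.18-fold, the fatty acid elongase Elovl6 at 1.13-fold and the cholesterol exporter Abcg1 at 1.12-fold. Respiratory chain genes were higher in 51 of 70 cases with a median of 0.035 (adjusted p = 0.0477, and adjusted p = 0.964 with an estimated correlation). Uqcrq of complex III was at 1.13-fold, the complex I genes Ndufs8 at 1.15-fold and Ndufb2 at 1.11-fold, and the ATP synthase gene Atp5h at 1.1-fold. Without the filter on dim probe sets each of the 4 calls at 24 h ended, with adjusted p values of 0.0742 for the cardiac and adipocyte lists, 0.0944 for the lipid list and 0.144 for the respiratory chain list. With probe sets averaged per gene the adipocyte (0.0531) and respiratory chain (0.253) calls ended. Without control replicate 2 the adipocyte, lipid and respiratory chain lists had adjusted p values of 0.448, 0.534 and 0.091, with adipocyte and lipid medians of 0.0495 and 0.0224. Without 24 h replicate 1 the adjusted p values were 0.093, 0.415 and 0.263, with a lipid median of 0.0101. Without 24 h replicate 2 they were 0.0731, 0.0602 and 0.606, with lipid and respiratory chain medians of 0.0584 and 0.0161. The adipocyte call also ended without 24 h replicate 3 (0.0633) and control replicate 3 (median 0.116, adjusted p = 0.463). Other medians grew without 1 array while the call held: adipocyte to 0.369 and lipid to 0.0878 without control replicate 1, lipid to 0.058 without 24 h replicate 3 or control replicate 3, and respiratory chain to 0.0665 without 24 h replicate 3. The lipid call ended without 48 h replicate 3 (0.0519), and the respiratory chain call without that array (0.0553), control replicate 1 (0.118) or control replicate 3 (0.289). Without the 3 replicate 1 arrays, an alternative chosen after seeing the data, the lipid list had a median of 0.0157 (adjusted p = 0.0726) and the respiratory chain list an adjusted p of 0.173. There the adipocyte list had a median of 0.326 (adjusted p = 1.9e-09) and the cardiac list one of -0.304 (adjusted p = 0.0032). The mean adipocyte change was -0.13 in the replicate 1 pair, 0.41 in the replicate 2 pair and 0.388 in the replicate 3 pair. In control replicates 1, 2 and 3 the list mean was 9.005, 8.30 and 8.34. Whether the lung samples held unequal amounts of fat tissue was not tested. Over all alternatives the adjusted p ran from 8.34e-08 to 0.988 for the cardiac list and from 1.9e-09 to 0.988 for the adipocyte list. It ran from 0.00102 to 0.988 for the lipid list and from 0.000243 to 0.988 for the respiratory chain list.

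None of the genes fixed in advance passed at 24 h, and the interval of each detected one included no change, with or without the replicate block. S100a8, which encodes a calcium-binding protein of neutrophils, had a log2 intensity of 12.3 ± 0.27 in control lungs and 11.92 ± 0.48 at 24 h (SD, n = 3), a fold of 0.771 (95% CI 0.361 to 1.65). Its partner S100a9 was at 0.825-fold (0.373 to 1.83). Fn1, the fibronectin gene, was at 0.984-fold (0.801 to 1.21) and the matrix protease gene Mmp9 at 0.864-fold (0.369 to 2.02). The collagen cross-linking enzyme gene Lox was at 1.05-fold (0.599 to 1.86), the stem cell factor receptor gene Kit at 0.924-fold (0.726 to 1.17) and the angiogenic factor gene Vegfa at 0.849-fold (0.545 to 1.32). Second probe sets of Lox and Vegfa had the opposite sign, at log2 changes of -0.02 and 0.06. Leaving out 1 array turned the sign of Lox (-0.21 without 24 h replicate 1, -0.0377 and -0.107 without control replicates 2 and 3), Fn1 (0.0446 without 24 h replicate 1, 0.0928 without control replicate 3) and Vegfa (0.0874 without 24 h replicate 2) on the log2 scale. These fits had no replicate block and left an array without its pair. Within the replicate 1, 2 and 3 pairs the log2 differences of Lox were small and positive, at 0.0528, 0.083 and 0.0957. Those of Fn1 (0.0623, 0.0598 and -0.19) and Vegfa (-0.0785, -0.804 and 0.176) differed in sign. Tnf, encoding an inflammatory cytokine, and Met, encoding the hepatocyte growth factor receptor, were detected on 0 of 9 arrays, with signals of 3.1 to 35.9 and 16.8 to 41.6 units. Of the lists near these genes, the niche and inflammation list had a median of -0.076 (adjusted p = 0.11) and the neutrophil list one of -0.13 (adjusted p = 0.27). With the preset correlation the niche list passed as lower without 24 h replicate 1 (median -0.176, adjusted p = 0.0163), 48 h replicate 1 (-0.0756, 0.0345) or control replicate 3 (-0.17, 0.0195), and without the 3 replicate 1 arrays (-0.128, 0.000447). The neutrophil list did so without 48 h replicate 1 (-0.13, 0.0416) and without the replicate 1 arrays (-0.199, 0.000348). With all arrays and an estimated correlation both had an adjusted p = 0.964.

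**Figure D2:**
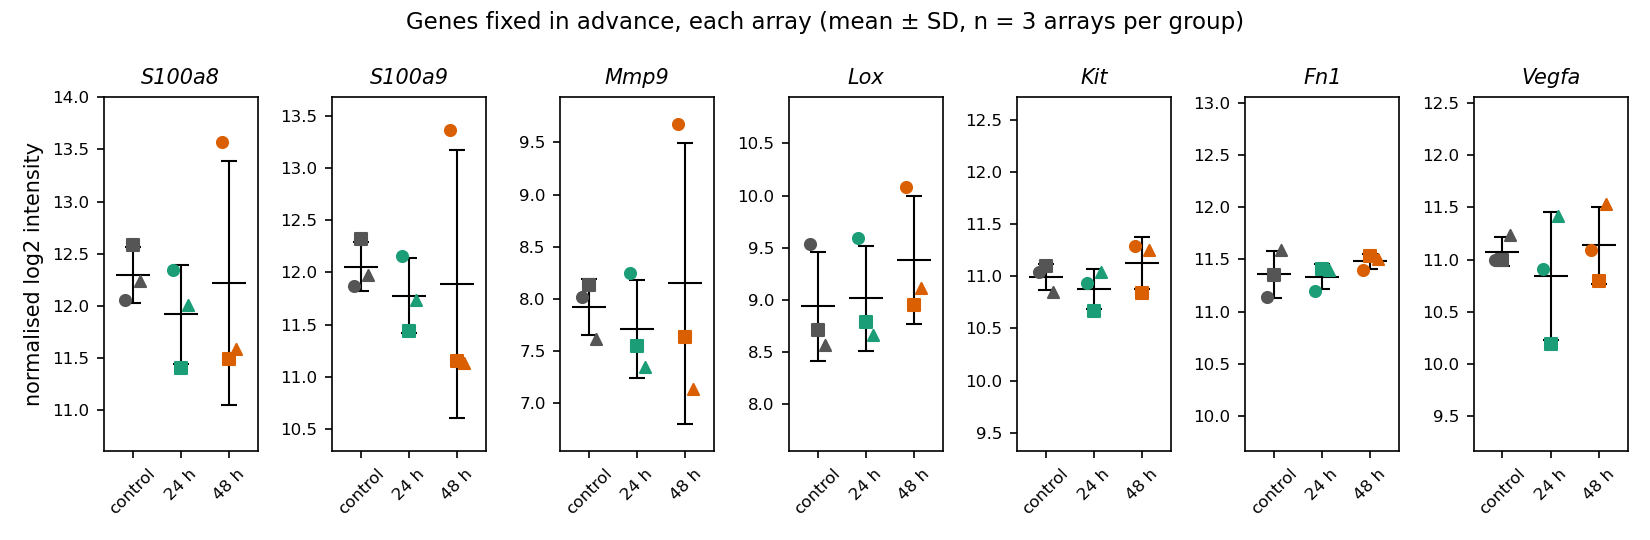
Normalised log2 intensity of 7 genes fixed in advance on each array, with mean ± SD of 3 arrays per group, where marker shape gives the replicate number and every panel spans the same number of log2 units. S100a8 lay at 12.3 ± 0.27 in control lungs, 11.92 ± 0.48 at 24 h and 12.22 ± 1.2 at 48 h.

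By limma, 0 of 15886 probe sets passed at 24 h (smallest adjusted p = 1). An unadjusted p under 0.05 was found for 185, where evenly spread p-values would give 794.3, and the replicate block gave 0 and 553. Differences between replicate numbers enter the spread in the fit without the block, with a median standard error of 0.153 against 0.107. The count of 185 therefore does not mean fewer changes than chance. The highest genes by moderated t, which did not pass, were Smr2, a salivary gland protein gene, at 1.43-fold (95% CI 1.19 to 1.73), the potassium channel partner Kcnip4 at 1.41-fold, and the zinc finger gene Zfp81 at 1.39-fold. Next came the T cell receptor gamma segment Trgv4 at 1.43-fold and Alb, encoding albumin, at 1.33-fold. The lowest were the RNA helicase gene Ddx6 at 0.726-fold (0.609 to 0.865), Lztr1, which encodes a ubiquitin ligase adaptor, at 0.529-fold (0.362 to 0.774), and Tcl1b3 at 0.606-fold. They were followed by the DNA methyltransferase gene Dnmt3b at 0.785-fold and Adamtsl4 at 0.767-fold. Other probe sets of Ddx6 had log2 changes of 0.18 and -0.04 against -0.46, and that of Lztr1 one of 0.03 against -0.92. Groups did not overlap for 620 probe sets (3.9%), against 10% by chance if arrays were exchangeable, which arrays paired by number are not. Of the 43 lists, 4 passed camera, 3 higher and 1 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.964, with 0 at an unadjusted p under 0.05) and 0 passed fry (smallest adjusted p = 0.988). No member of the 4 lists passed (0 over all probe sets and 0 adjusted over the list alone), with 1 adipocyte and 1 lipid gene at an unadjusted limma p under 0.05. The block called 1 adipocyte gene when adjusted over the list alone. The count of 4 lists became 0 without 24 h replicate 2 or control replicate 2, 2 without 48 h replicate 3, 7 without 24 h replicate 1 or control replicate 3, and 8 without 24 h replicate 3.

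At 48 h after exosomes, cell cycle, extracellular matrix, type I interferon and immediate early genes rose as groups, and B cell genes fell, again with the preset correlation and without a single gene past the threshold. Each of these 5 calls ended with an estimated correlation (adjusted p = 0.609 with an estimated correlation). Cell cycle genes were higher than control in 30 of 32 cases, with a median log2 change of 0.17 (adjusted p = 9.99e-10, and adjusted p = 0.609 with an estimated correlation). Mki67, the proliferation marker, was at 1.27-fold (95% CI 1 to 1.6), Top2a, the topoisomerase that untangles chromosomes, at 1.28-fold (0.989 to 1.66), the mitotic cyclin gene Ccnb2 at 1.22-fold (1.01 to 1.48) and Uhrf1, which maintains DNA methylation, at 1.18-fold. The mean change of the list was 0.40 in the replicate 1 pair, -0.013 in the replicate 2 pair and 0.096 in the replicate 3 pair. The call held in each fit that left out 1 array, but without control replicate 1 the median fell to 0.0708 (adjusted p = 0.0211), and without the 3 replicate 1 arrays it was 0.042 (adjusted p = 0.16). All 14 B cell genes were lower, with a median of -0.25 (adjusted p = 1.22e-05, and adjusted p = 0.609 with an estimated correlation). Ms4a1, the gene of the surface antigen CD20, was at 0.776-fold (0.615 to 0.979), the antigen receptor subunit gene Cd79b at 0.685-fold (0.461 to 1.02), the coreceptor gene Cd22 at 0.795-fold and the adaptor gene Blnk at 0.78-fold. Without 48 h replicate 1 the B cell list had a median of -0.139 (adjusted p = 0.0573). Its median was -0.393 without 48 h replicate 2 and -0.421 without control replicate 1, with the call kept.

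Matrix and remodelling genes were higher at 48 h in 23 of 30 cases (median 0.14, adjusted p = 8.89e-05, and adjusted p = 0.609 with an estimated correlation). Thbs1, encoding the adhesive matrix glycoprotein thrombospondin, was at 1.47-fold (95% CI 1.13 to 1.9), the matricellular gene Ccn1 at 1.37-fold (1.03 to 1.82), the proteoglycan gene Vcan at 1.31-fold and the lysyl oxidase-like gene Loxl4 at 1.23-fold, with a second Loxl4 probe set at a log2 change of -0.43. Type I interferon genes were higher in 20 of 23 cases (median 0.11, adjusted p = 0.000145, and adjusted p = 0.609 with an estimated correlation). The antiviral genes included Mx1 at 1.29-fold (1.07 to 1.54), Oasl2 at 1.26-fold (1.01 to 1.57), Rsad2 at 1.34-fold and the GTPase gene Iigp1 at 1.34-fold. Interferon gamma and antigen presentation genes were higher in 15 of 22 cases (median 0.060, adjusted p = 0.00664, and adjusted p = 0.65 with an estimated correlation). Of the immunity GTPase genes, Igtp was at 1.31-fold, Irgm1 at 1.29-fold, Irgm2 at 1.22-fold and Gbp6 at 1.38-fold. Without the replicate 1 arrays the matrix list had a median of 0.031 (adjusted p = 0.088) and the type I interferon list one of -0.0033 (adjusted p = 0.53). The matrix call ended without 48 h replicate 1 (median 0.0381, adjusted p = 0.168), and the type I interferon call without that array (adjusted p = 0.104) or control replicate 1 (median 0.0552, adjusted p = 0.119). With their calls kept, the matrix median was 0.0858 without control replicate 3, and without control replicate 2 the type I interferon median was 0.208 and the interferon gamma median 0.0909. The interferon gamma call ended without 48 h replicate 2 (0.0686), 48 h replicate 3 (0.0773) or control replicate 3 (0.193).

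Immediate early genes, which cells switch on within minutes of stimulation, were higher at 48 h in 18 of 24 cases (median 0.17, adjusted p = 0.000104, and adjusted p = 0.609 with an estimated correlation). Fosb was at 1.44-fold (95% CI 0.93 to 2.22), Maff at 1.23-fold, Klf2 at 1.18-fold and Ccn1 at 1.37-fold. Glucocorticoid response genes were higher in 14 of 18 cases (median 0.11, adjusted p = 0.00125, and adjusted p = 0.65 with an estimated correlation). The metallothionein gene Mt2 was at 1.24-fold (1.01 to 1.52), the pyruvate dehydrogenase kinase gene Pdk4 at 1.45-fold, Errfi1 at 1.21-fold and Angptl4 at 1.33-fold. Erythroid genes were higher in 10 of 11 cases (median 0.11, adjusted p = 0.0319, and adjusted p = 0.65 with an estimated correlation). The haem synthesis gene Alas2 was at 1.35-fold, the globin gene Hbb-b2 at 1.32-fold, Trim10 at 1.26-fold and the transferrin receptor gene Tfrc at 1.08-fold. A second Tfrc probe set had a log2 change of -0.39. With the replicate block the erythroid list had an adjusted p of 0.0501. Cardiac muscle genes were lower in 16 of 18 cases (median -0.21, adjusted p = 0.00459, and adjusted p = 0.97 with an estimated correlation). Ryr2 was at 0.696-fold (0.49 to 0.988), the troponin genes Tnnt2 at 0.773-fold and Tnni3 at 0.762-fold and Myh6 at 0.804-fold. Without 48 h replicate 1 the immediate early, glucocorticoid and erythroid calls ended (adjusted p = 0.0765, 0.526 and 0.768, with medians of 0.109, 0.0412 and -0.0094). The glucocorticoid call also ended without 48 h replicate 3 (0.0773) and the erythroid call without control replicate 3 (median 0.0654, adjusted p = 0.614). With the call kept, the immediate early median was 0.264 without 48 h replicate 2 and 0.045 without control replicate 3 (adjusted p = 0.0445). The glucocorticoid median was 0.303 without 48 h replicate 2, and 0.199, 0.165 and 0.176 without control replicates 1, 2 and 3. The cardiac list turned to a median of 0.11 without 48 h replicate 3 (adjusted p = 0.0972) and lost its call without control replicate 1 (0.451) or control replicate 2 (0.111). Its median was -0.392 without 48 h replicate 1, -0.369 without 48 h replicate 2 and -0.361 without control replicate 3, with the call kept. Within each same-number pair the mean of the cardiac list was lower at 48 h than in control. Without the replicate 1 arrays the glucocorticoid and erythroid lists had medians of 0.0138 and 0.0197 (adjusted p = 0.16 and 0.449), and the cardiac list one of -0.319 (adjusted p = 0.00557). Without the filter the erythroid (adjusted p = 0.203) and cardiac (0.0969) calls ended, and with probe sets averaged per gene the erythroid call did (0.116). Over all alternatives the adjusted p of the 9 lists at 48 h had a lowest value between 2.79e-13 (cell cycle) and 0.00426 (erythroid) and a highest value of 0.978.

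Among the genes fixed in advance, S100a8 was at 0.947-fold at 48 h (95% CI 0.443 to 2.02) and S100a9 at 0.89-fold (0.402 to 1.97). Mmp9 was at 1.17-fold (0.5 to 2.73). These 3 values rested on 48 h replicate 1. Within the replicate 1, 2 and 3 pairs the log2 differences were 1.51, -1.1 and -0.65 for S100a8, 1.5, -1.16 and -0.839 for S100a9, and 1.66, -0.502 and -0.482 for Mmp9. Without that array the log2 changes were -0.755, -0.909 and -0.539. Those of S100a8 and S100a9 turned positive without 48 h replicate 2 (0.283 and 0.197) or 48 h replicate 3 (0.234 and 0.206), and that of S100a8 without control replicate 2 (0.0665). Lox was at 1.36-fold (0.773 to 2.39), Fn1 at 1.09-fold (0.886 to 1.34), Kit at 1.1-fold (0.863 to 1.39) and Vegfa at 1.04-fold (0.668 to 1.62). With the replicate block the interval of Lox was 1.17 to 1.58 (unadjusted p = 0.0017, adjusted p = 0.999), its log2 differences within the pairs being 0.547, 0.244 and 0.541, and the intervals of the other 6 genes included no change. Vegfa turned to -0.138 on the log2 scale without 48 h replicate 3. The log2 change of Lox fell from 0.444 to 0.093 without 48 h replicate 1 and rose to 0.743 without control replicate 1. Fn1 fell from 0.122 to 0.012 without control replicate 1, and Kit from 0.133 to 0.05 without 48 h replicate 1. Second probe sets of Mmp9 and Vegfa had log2 changes of -0.21 and -0.36. The niche and inflammation list had a median of 0.036 (adjusted p = 0.846), the neutrophil list one of 0.059 (adjusted p = 0.734), and the monocyte and macrophage list one of 0.049 (adjusted p = 0.186). The array of 48 h replicate 1 stood apart in neutrophil genes, with a list mean of 9.89 against 8.52 to 9.07 on the other 8. Without it the neutrophil list was lower at 48 h (median -0.514, adjusted p = 1.1e-05), as was the niche list (-0.0819, 0.00653), with the preset correlation. The same held without the 3 replicate 1 arrays (-0.526, 5.77e-06 and -0.0598, 0.0226), while without 48 h replicate 2 the neutrophil list was higher (0.308, 0.0423). The monocyte list passed as higher without 48 h replicate 3 (0.0648, 0.0357). With all arrays and an estimated correlation the neutrophil and niche lists had an adjusted p = 0.97 and the monocyte list an adjusted p = 0.65. The hypoxia and glycolysis list had a median of 0.0031 (adjusted p = 0.927) and the exosome and vesicle trafficking list one of -0.016 (adjusted p = 0.987). RNA of the melanoma cells themselves was sought through pigment cell genes. The melanocyte genes Dct, Pmel, Mc1r, Slc45a2 and Trpm1 were detected on 0 of 9 arrays, Tyrp1 on 1 control array and Gpr143 on 1 exosome array. A single probe set of the tyrosinase gene Tyr was detected on 4 arrays, 1 of them a control. Genes of the list that were detected in control lungs too were Oca2 on 6 arrays, 2 of them controls, Sox10 on 8, with all 3 controls, and Mitf, Gpnmb, Rab38 and Rab27a on 9. The melanocyte and melanoma list, with 5 measured genes, had medians of -0.098 at 24 h (adjusted p = 0.861) and -0.053 at 48 h (adjusted p = 0.875).

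By limma, 0 of 15886 probe sets passed at 48 h (smallest adjusted p = 1), 221 had an unadjusted p under 0.05, and the replicate block gave 0 and 739. The highest genes by moderated t, which did not pass, were Cdip1, a p53 target linked to cell death, at 1.66-fold (95% CI 1.31 to 2.11), the immunoglobulin gene Ighg3 at 1.99-fold (1.4 to 2.82), the histone variant gene Macroh2a2 at 1.62-fold, Glipr2 at 1.37-fold and 1700097N02Rik at 1.41-fold. A second Cdip1 probe set had a log2 change of -0.05 against 0.735. The lowest were the nuclear pore gene Nup188 at 0.68-fold (0.556 to 0.832), the proton pump gene Atp6v1b1 at 0.698-fold, the immunoglobulin segment Igkv8-30 at 0.511-fold (0.344 to 0.757), Nap1l5 at 0.615-fold and the annexin gene Anxa9 at 0.707-fold. Groups did not overlap for 715 probe sets (4.5%), against 10% by chance with the same reservation. Of the 43 lists, 9 passed camera, 7 higher and 2 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.609, with 3 at an unadjusted p under 0.05) and 0 passed fry (smallest adjusted p = 0.978). No member of the 9 lists passed (0 over all probe sets and 0 adjusted over the list alone), with 3 matrix genes and 2 cell cycle genes among those at an unadjusted limma p under 0.05. The block called 2 matrix genes when adjusted over the list alone.

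**Figure D3:**
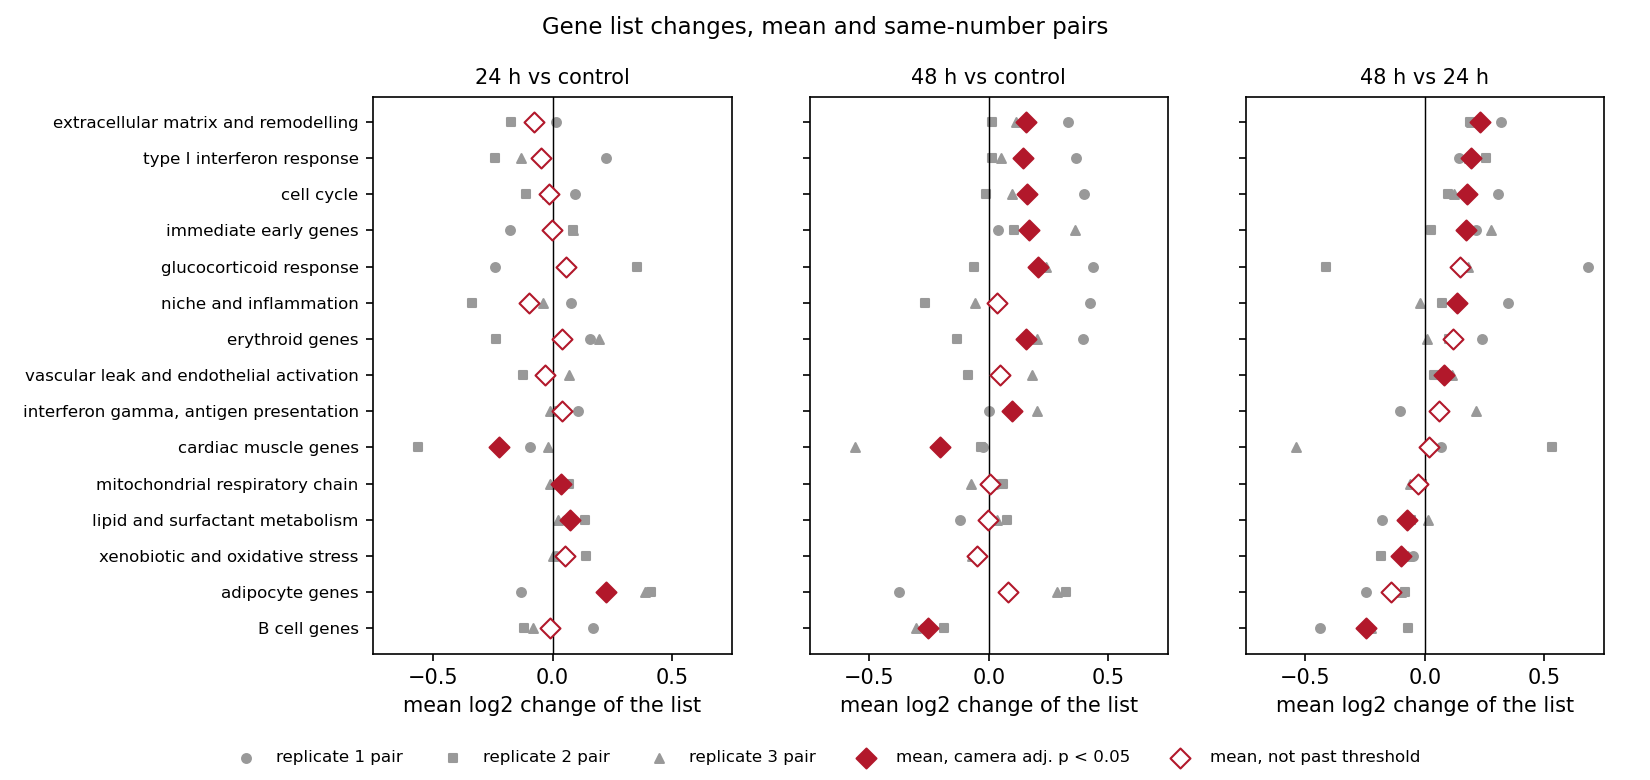
Mean log2 change of each gene list that passed camera in at least 1 of 3 comparisons (diamonds, filled where adjusted p is under 0.05) and the difference within each pair of arrays with the same replicate number (grey markers). The cell cycle list at 48 h against control ran from -0.013 in the replicate 2 pair to 0.40 in the replicate 1 pair.

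Between 24 h and 48 h, matrix, cell cycle and type I interferon genes rose and B cell genes fell, as tested directly on the difference between the times with the preset correlation. Each of these 4 calls ended with an estimated correlation (adjusted p = 0.18 for the matrix list and adjusted p = 0.567 for the others, with an estimated correlation), and no single gene passed. Matrix genes were higher at 48 h in 27 of 30 cases, with a median log2 difference of 0.21 (adjusted p = 1.17e-08, and adjusted p = 0.18 with an estimated correlation). Thbs1 was at 1.56-fold (95% CI 1.21 to 2.02), Ccn1 at 1.44-fold (1.08 to 1.91), the collagen gene Col5a1 at 1.26-fold (1 to 1.59) and the laminin gene Lamc1 at 1.21-fold. Cell cycle genes were higher in 30 of 32 cases (median 0.19, adjusted p = 2.35e-09, and adjusted p = 0.567 with an estimated correlation). Rrm2, which supplies deoxynucleotides, was at 1.34-fold (1.06 to 1.71), the mitotic kinesin genes Kif22 at 1.22-fold and Kif11 at 1.29-fold, and the anaphase activator gene Cdc20 at 1.32-fold. Type I interferon genes were higher in 20 of 23 cases (median 0.17, adjusted p = 2.41e-05, and adjusted p = 0.567 with an estimated correlation). Oas2 was at 1.56-fold (1.01 to 2.43), Oasl2 at 1.36-fold (1.09 to 1.69), the nucleic acid sensor gene Zbp1 at 1.28-fold and Mx1 at 1.17-fold. Without 48 h replicate 1 the medians of the matrix and interferon lists were 0.108 (adjusted p = 0.00326) and 0.115 (adjusted p = 0.036), and without the replicate 1 arrays that of the cell cycle list was 0.115. Each of these 3 lists was higher in all 3 same-number pairs and kept its call in each fit without 1 array and in the fit without the replicate 1 arrays (adjusted p = 7.81e-06, 0.00304 and 7.81e-06). The highest adjusted p over all alternatives was 0.644 for the matrix list, 0.929 for the cell cycle list and 0.911 for the interferon list. The value of 0.929 is that with the labels of the series table, which sets the 24 h files against the control files, another comparison.

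B cell genes were lower at 48 h than at 24 h in 12 of 14 cases (median -0.23, adjusted p = 0.000151, and adjusted p = 0.567 with an estimated correlation). Ms4a1 was at 0.774-fold (95% CI 0.613 to 0.976), the immunoglobulin M gene Ighm at 0.665-fold, the low-affinity IgE receptor gene Fcer2a at 0.666-fold and Cd22 at 0.793-fold. Further probe sets of Ighm ran from -1.04 to 0.02 on the log2 scale. Immediate early genes were higher in 20 of 24 cases (median 0.094, adjusted p = 0.00118, and adjusted p = 0.567 with an estimated correlation). Fosb was at 1.6-fold (1.03 to 2.47), the cytokine signalling inhibitor gene Socs3 at 1.4-fold and Junb at 1.2-fold. In the fit without 48 h replicate 1 the B cell list had a median of -0.0683 (adjusted p = 0.119) and the immediate early list an adjusted p of 0.139. In the fit without 48 h replicate 2 the medians were -0.401 and 0.157, with both calls kept. Without the replicate 1 arrays the B cell list had an adjusted p of 0.149 and the immediate early list a median of 0.0235 (adjusted p = 0.0388). The highest adjusted p over all alternatives was 0.953 for the B cell list, with the series-table labels and thus for other groups' files, and 0.911 for the immediate early list. Niche and inflammation genes were higher in 21 of 28 cases (median 0.16, adjusted p = 0.0497, and adjusted p = 0.73 with an estimated correlation). Timp1, a protease inhibitor gene, was at 1.27-fold, Kit at 1.19-fold and Loxl3 at 1.15-fold, while the chemokine gene Cxcl12 was at 0.799-fold. Neutrophil genes moved with this list: 9 of 9 were higher (median 0.219, adjusted p = 0.0622, and adjusted p = 0.73 with an estimated correlation). Their mean difference was 0.913 in the replicate 1 pair, -0.136 in the replicate 2 pair and -0.0744 in the replicate 3 pair. The neutrophil list was lower without 48 h replicate 1 (median -0.313, adjusted p = 0.0316). It passed as higher without 24 h replicate 1 (0.375, 0.0316), 48 h replicate 2 (0.477, 0.00102) or 48 h replicate 3 (0.485, 0.00551). Vascular leak and endothelial activation genes were higher in 14 of 21 cases (median 0.077, adjusted p = 0.0497, and adjusted p = 0.567 with an estimated correlation). The urokinase gene Plau was at 1.21-fold, the adhesion molecule gene Selp at 1.14-fold and the junction genes Cdh5 and Tjp1 both at 1.12-fold. A second Cdh5 probe set had a log2 difference of -0.03. As the list holds junction genes beside adhesion and coagulation genes, its direction does not stand for vascular leak. Lipid genes were lower in 15 of 21 cases (median -0.050, adjusted p = 0.0497, and adjusted p = 0.73 with an estimated correlation). The malic enzyme gene Me1 was at 0.766-fold (0.627 to 0.936), Srebf1 at 0.833-fold, the isoprenoid synthesis gene Fdps at 0.836-fold and Acaca at 0.854-fold. Xenobiotic and oxidative stress genes were lower in 18 of 25 cases (median -0.094, adjusted p = 0.0497, and adjusted p = 0.567 with an estimated correlation). The glutathione peroxidase gene Gpx2 was at 0.833-fold, the glutathione S-transferase gene Gsta4 at 0.843-fold, Aldh3a1 at 0.791-fold and Cyp2b10 at 0.862-fold.

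These last 4 lists lay close to the threshold. Without 48 h replicate 1 the adjusted p was 0.445 for the niche list (median -0.0062), 0.174 for the vascular list, 0.256 for the lipid list and 0.137 for the xenobiotic list (median -0.035). Without 24 h replicate 2 it was 0.684 for the niche, 0.404 for the vascular and 0.301 for the xenobiotic list (medians 0.0493, 0.0306 and -0.0343). Without 24 h replicate 3 it was 0.0959 for the niche (median 0.0973), 0.0552 for the lipid and 0.0925 for the xenobiotic list. Without 48 h replicate 2 both the lipid and the xenobiotic list were at 0.228, and without 24 h replicate 1 the vascular list was at 0.0683 (median 0.12) and the lipid list at 0.398. With the call kept, the niche median was 0.248 without 48 h replicate 2, the vascular one 0.119 without 24 h replicate 3, the lipid one -0.114 without 48 h replicate 3 and the xenobiotic one -0.16 without 24 h replicate 1. The vascular call ended without 48 h replicate 3 (0.609) and the niche call without control replicate 3 (0.0516). Without the replicate 1 arrays the niche, vascular and lipid lists had adjusted p values of 0.721, 0.252 and 0.895 (medians 0.0785, 0.134 and -0.00265). The filter left out ended the niche (0.238, median 0.0927), lipid (0.0617) and xenobiotic (0.0617) calls. Averaging probe sets per gene ended the niche (0.0994), vascular (0.0994) and xenobiotic (0.168, median -0.029) calls, median centring the niche (0.0566) and vascular (0.0506) calls, and no further normalisation the vascular call (0.0504). Over all alternatives the adjusted p ran from 0.00377 to 0.911 for the niche and vascular lists, from 0.00175 to 0.911 for the lipid list and from 0.0057 to 0.911 for the xenobiotic list. With the replicate block the vascular list (adjusted p = 0.0573) and the lipid list (adjusted p = 0.0653) did not pass, while smooth muscle genes (adjusted p = 0.007) and adipocyte genes (adjusted p = 0.0415) did. With the block and an estimated correlation these had adjusted p = 0.715 and adjusted p = 0.739. S100a8 was at 1.23-fold (95% CI 0.574 to 2.62) and S100a9 at 1.08-fold (0.487 to 2.38). Mmp9 was at 1.35-fold (0.578 to 3.16). The direction of these 3 again rested on 48 h replicate 1. Pair differences on the log2 scale were 1.22, 0.0843 and -0.42 for S100a8, 1.21, -0.284 and -0.6 for S100a9, and 1.43, 0.0857 and -0.208 for Mmp9. The log2 differences turned to -0.38, -0.633 and -0.327 in the fit without that array. S100a9 also turned without 24 h replicate 2 (-0.0617), as did Vegfa (-0.0285). Lox was at 1.29-fold (0.732 to 2.27), Fn1 at 1.11-fold (0.899 to 1.36) and Vegfa at 1.23-fold (0.786 to 1.91). With the block the interval of Lox was 1.11 to 1.5 (unadjusted p = 0.0051, adjusted p = 0.779). Its log2 differences within the pairs were 0.494, 0.161 and 0.445. Its log2 difference of 0.366 fell to 0.016 without 48 h replicate 1 and rose to 0.654 without 24 h replicate 1. Second probe sets of Mmp9 and Vegfa had log2 differences of -0.03 and -0.42.

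By limma, 0 of 15886 probe sets differed between 48 h and 24 h (smallest adjusted p = 1), 281 had an unadjusted p under 0.05, and the replicate block gave 0 (smallest adjusted p = 0.688) and 885. The highest genes by moderated t, which did not pass, were Tcl1b3 at 1.91-fold (95% CI 1.4 to 2.6), the collagen gene Col6a3 at 1.38-fold (1.17 to 1.62), the ATP synthase gene Atp5md at 1.45-fold, Thbs1, and the condensin gene Ncapg2 at 1.46-fold. The lowest were the immunoglobulin segment Igkv5-39 at 0.723-fold (0.613 to 0.853), the D-aspartate oxidase gene Ddo at 0.665-fold, Actrt1 at 0.71-fold, the mRNA cleavage factor gene Cpsf4 at 0.706-fold and Mrm1 at 0.775-fold. Groups did not overlap for 725 probe sets (4.56%), against 10% by chance with the same reservation. Of the 43 lists, 9 passed camera, 6 higher and 3 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.18, with 1 at an unadjusted p under 0.05) and 0 passed fry (smallest adjusted p = 0.595). No member of the 9 lists passed (0 over all probe sets and 0 adjusted over the list alone), with 3 matrix, 2 cell cycle, 2 interferon and 2 immediate early genes among those at an unadjusted limma p under 0.05. The block called 1 matrix gene when adjusted over the list alone. The count of 9 lists became 14 without 24 h replicate 1 and 15 without 48 h replicate 3.

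With both times averaged, cardiac muscle and B cell genes fell against control and cell cycle, immediate early, glucocorticoid response and interferon gamma genes rose with the preset correlation, all with an adjusted p = 0.969 with an estimated correlation. Cardiac genes were lower in 17 of 18 cases (median log2 change -0.23, adjusted p = 0.000482). Ryr2 was at 0.738-fold (95% CI 0.545 to 1) and Myh6 at 0.745-fold, Tnnt2 at 0.78-fold and Mybpc3 at 0.839-fold. B cell genes were lower in 12 of 14 cases (median -0.14, adjusted p = 0.0103). The receptor subunit gene Cd79b was at 0.803-fold, Cd79a at 0.817-fold, Ms4a1 at 0.882-fold and the coactivator gene Pou2af1 at 0.872-fold. Cell cycle genes were higher in 29 of 32 cases (median 0.071, adjusted p = 0.00128). Uhrf1 was at 1.13-fold, Ccnb2 at 1.14-fold, the mitotic kinase gene Cdk1 at 1.16-fold and Mki67 at 1.15-fold. Glucocorticoid genes were higher in 15 of 18 cases (median 0.14, adjusted p = 0.0206). Mt2 was at 1.13-fold, Pdk4 at 1.27-fold, Errfi1 at 1.14-fold and Fkbp5 at 1.24-fold. Immediate early genes were higher in 19 of 24 (median 0.077, adjusted p = 0.0214). Maff was at 1.17-fold, Klf2 and Myc at 1.16-fold and Ccn1 at 1.14-fold. Interferon gamma genes were higher in 17 of 22 cases (median 0.045, adjusted p = 0.0131). Igtp was at 1.23-fold, Irgm1 at 1.18-fold, Irgm2 at 1.15-fold and the immunoproteasome gene Psmb9 at 1.1-fold. The cell cycle list lost its call and its direction without control replicate 1 (median -0.0025, adjusted p = 0.927) and without the replicate 1 arrays (median -0.0069, adjusted p = 0.988). With its call kept, its median was 0.0457 without 24 h replicate 3 and 0.118 without control replicate 2. The cardiac call ended without control replicate 1 (median -0.145, adjusted p = 0.317) or 48 h replicate 3 (-0.0532, 0.0995), and its median was -0.395 without control replicate 3. The B cell call ended without 48 h replicate 1 (0.228), control replicate 2 (median -0.0767, adjusted p = 0.862) or control replicate 3 (0.0578), and its median was -0.23 without control replicate 1 and -0.216 without the replicate 1 arrays. The interferon gamma call ended without 24 h replicate 1 (0.29), 48 h replicate 3 (0.0621) or control replicate 3 (0.362), and its median was 0.0824 without 24 h replicate 3 and 0.0704 without control replicate 2. The immediate early call ended without 24 h replicate 1 (median 0.0498, adjusted p = 0.124), 48 h replicates 1 (0.236) and 3 (0.0995), and control replicates 2 (median 0.0398, adjusted p = 0.383) and 3 (0.00306, 0.787). Its median was 0.164 without control replicate 1 and 0.15 without the replicate 1 arrays. The glucocorticoid call ended without 24 h replicates 2 (median 0.0831, adjusted p = 0.208) and 3 (0.0771), 48 h replicates 1 (median 0.0437, adjusted p = 0.382) and 3 (0.0909, 0.0995), and control replicates 2 (0.0947, 0.32) and 3 (adjusted p = 0.0578). Its median was 0.0929 without the replicate 1 arrays (adjusted p = 0.00167). Without the filter the immediate early (adjusted p = 0.0651) and glucocorticoid (0.124) calls ended. Over all alternatives the highest adjusted p was 0.988 for the cell cycle list and 0.975 for the other 5.

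In the averaged comparison, limma called 0 of 15886 probe sets (smallest adjusted p = 1), 172 had an unadjusted p under 0.05, and the replicate block gave 0 and 568. The highest genes by moderated t, which did not pass, were Smr2 at 1.37-fold (95% CI 1.17 to 1.62), Ighg3 at 1.75-fold (1.29 to 2.37), Cdip1 at 1.46-fold, Macroh2a2 at 1.5-fold and Zfp81 at 1.37-fold. The lowest were Atp6v1b1 at 0.728-fold, Nup188 at 0.742-fold, Nap1l5 at 0.659-fold, Ddx6 at 0.778-fold and Sh3bp4 at 0.798-fold. Among the genes fixed in advance, S100a8 was at 0.854-fold (0.443 to 1.65), S100a9 at 0.857-fold (0.431 to 1.7), and Mmp9 at 1-fold (0.481 to 2.1). Lox was at 1.2-fold (0.734 to 1.95), Fn1 at 1.04-fold (0.866 to 1.24), Kit at 1.01-fold (0.817 to 1.24) and Vegfa at 0.941-fold (0.64 to 1.38). Values near 1-fold changed sign with 1 array left out: on the log2 scale Mmp9 was at -0.375 without 48 h replicate 1, -0.127 without 24 h replicate 1 and -0.145 without control replicate 3, Vegfa at 0.0732 without 24 h replicate 2 and Fn1 at -0.0599 without control replicate 1. Kit ran to -0.0621 (without control replicate 3). S100a8 moved from -0.227 to -0.565 and S100a9 from -0.223 to -0.593 without 48 h replicate 1. Closest to no change were S100a8 at -0.046 without 48 h replicate 2 and S100a9 at -0.04 without 48 h replicate 3. With the block the interval of Lox was 1.05 to 1.37 (unadjusted p = 0.014, adjusted p = 1). Its log2 change of 0.26 fell to 0.085 without 48 h replicate 1 and to 0.076 without control replicate 3. It rose to 0.56 without control replicate 1. Second probe sets of Cdip1, Kit, Fn1 and Mmp9 had log2 changes of -0.02, -0.05, -0.01 and -0.20, and those of Ddx6 of 0.16 and -0.06. Of the 43 lists, 6 passed camera, 4 higher and 2 lower. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05) and 0 passed fry (smallest adjusted p = 0.951). In each of these 6 lists 0 members passed over all probe sets and 0 adjusted over the list alone, with 1 cardiac gene at an unadjusted limma p under 0.05.

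The 24 h and 48 h changes against control correlated with r = 0.396 across 15886 probe sets, which are not independent replicates, and 62.2% had the same sign. Both comparisons share the 3 control arrays, and unchanged groups simulated 100 times against those controls gave r = 0.5 (0.47 to 0.524) and 66.7% of the same sign. The observed covariance of 0.00773 lay below the simulated 0.00838, a difference of -0.000649. Without control replicate 1 the correlation was 0.694 and without 24 h replicate 1 it was 0.268. No split of the 3 controls leaves 2 arrays for each time, so the part of the shared controls was not separated from this correlation.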

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

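The splits for counts of probe sets, the test of whether cardiac genes move together, the test of the correlation between cell cycle genes and the share of their change kept without 1 array were chosen after the results were seen. The change between 24 h and 48 h was tested directly for 43 gene lists, and 9 differed with camera's preset correlation. The lists that were higher at 48 h than at 24 h were matrix (median log2 0.206; -0.0778 against control at 24 h and 0.138 at 48 h), cell cycle (0.188; 0.000869 and 0.173), type I interferon (0.173; -0.0184 and 0.113), niche and inflammation (0.156; -0.0756 and 0.036), immediate early (0.0938; -0.0134 and 0.174) and vascular leak genes (0.0773; -0.024 and 0.0612). Those that were lower were B cell (-0.232; -0.0645 and -0.251), xenobiotic (-0.0941; 0.0425 and -0.0452) and lipid genes (-0.0504; 0.0377 and 0.0151). With an estimated correlation none of the 9 differences passed, the smallest adjusted p being 0.18 for matrix genes, and no single gene differed by limma (0 probe sets, with 281 at an unadjusted p under 0.05 and 0 with the replicate block).

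Other splits of the same arrays bear on these counts. For 24 h against control, 8 of the 10 splits gave as many lists (real 4, highest other 13), for 48 h against control 7 of 10 (real 9, highest other 16) and for 48 h against 24 h 7 of 10 (real 9, highest other 21). Among the 4 splits that part all 3 same-number pairs, as the real one does, 3, 3 and 2 gave as many (highest other 13, 12 and 9). Such small numbers of splits cannot give a share under 0.05. For both times against control, 65 of 84 splits gave at least the real 6 lists (highest other 20), and 17 of the 27 splits that part all pairs did (highest other 18), so chance is not excluded there. A count of 0 probe sets is matched by any split, so the splits say nothing about it (10 of 10 in each of the 3 comparisons, with highest others of 0, 1 and 0, and 84 of 84 for the average). The split that set the 3 replicate 1 arrays against the other 6 called 2892 probe sets, which points to a structure of the samples by replicate number. The same kind of split called 58 probe sets for the replicate 3 arrays and 1 for the replicate 2 arrays.

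The cell cycle list at 48 h was higher in 30 of 32 genes against control and against 24 h. Of the fits without 1 array, 0 lost the call. Against control the median fell from 0.173 to 0.0708 without control replicate 1 (adjusted p = 0.0211), a share of 0.409. These fits had no replicate block. The fall therefore does not tell an effect of that array from the difference between replicate numbers that its removal leaves unpaired. Against 24 h the smallest share kept was 0.84, in fits with the same limit, so that share does not decide about a single array. The list means of replicates 1, 2 and 3 were 7.67, 7.54 and 7.62 at 48 h. At 24 h they were 7.36, 7.44 and 7.5. Each pair was thus higher at 48 h, the replicate 1 pair by most, and without the replicate 1 arrays the median was 0.115. The genes also moved together between arrays once group and replicate means were removed, with an estimated correlation of 0.27, and the call ended with that correlation and the block (adjusted p = 0.8 against control and 0.715 against 24 h). Shared fluctuation of a proliferating fraction between lungs therefore stays open, as does a response to exosomes, which 3 arrays per group did not separate from it. Against control the change also rested on the replicate 1 pair (mean 0.40, against -0.013 and 0.096), and without the replicate 1 arrays the median was 0.0421 (adjusted p = 0.16).

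The cardiac muscle list was lower at both times with the preset correlation, and neither call held with an estimated correlation. Without 48 h replicate 3, in a fit without the block that left control replicate 3 unpaired, the list's median at 48 h turned to 0.114. Its 18 members moved together within groups and replicates: the median correlation of a member with the mean of the others was 0.897 (0.198 to 0.998), which is consistent with unequal amounts of heart or pulmonary vein muscle in the lung samples. The list mean spanned at least 0.469 between the arrays of a group and 0.224 between group means, a ratio of 2.09, and groups fell in different orders in different replicate sets. All 6 exosome arrays lay below the control array of their own number, 2 of them by more than the within-group SD of 0.393. Unequal tissue may set the difference by itself, and an effect of exosomes on heart muscle genes was not tested apart from it.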

How the results depend on the processing

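Fits without the 3 replicate 1 arrays or without further normalisation, and list tests on median-centred values, on series-table values or with the block and an estimated correlation, were added after the data were seen. The count of 0 probe sets past the threshold was the same under every alternative run in all 4 comparisons. Without the block, limma recovered 4 of 67 simulated 1.5-fold changes, so its count of 0 says little about changes of that size. With the replicate block it recovered 53 of 67, with 13 false calls, and that fit also gave 0 in all 4. Alternatives without background correction and with a slide or scan block were not run, since the files give no uncorrected column and no batch, and a fit of only the groups compared has no form for the average of both times. The number of arrays and dim signals near the detection limit bound what could be seen.

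The correlation of 24 h and 48 h changes (0.396) was 0.59 with array weights and 0.268 to 0.694 with 1 array left out (0.694 without control replicate 1, 0.548 without control replicate 3, 0.268 without 24 h replicate 1). With separate controls it was -0.443 and -0.479 (control 1 alone for 24 h or for 48 h), -0.137 and -0.0782 (control 2) and -0.219 and -0.215 (control 3). Each of these sets a control of 1 replicate number against those of the others, which by itself lowers the correlation, so they say nothing about the responses. Lists past the threshold numbered 4, 9, 9 and 6 for 24 h, 48 h, 48 h against 24 h and the average. They were 0 in all 4 with an estimated correlation, with fry, and with the replicate block and an estimated correlation. The replicate block gave 3, 8, 9 and 6 and changed no call other than those given with the lists. At 24 h the count was 2 with probe sets averaged per gene, and 1 without the filter, which ended each of the 4 calls and added skeletal muscle genes (median 0.76, adjusted p = 0.00336). With the filter that list had an adjusted p = 0.503, and adjusted p = 0.964 with an estimated correlation. Its mean was 9.34 in 24 h replicate 1 and 6.51 to 7.49 on the other 8 arrays, and its mean changes within the pairs were 1.88, -0.452 and -0.202. It was 9 with series-table values, 9 without the replicate 1 arrays and 0 to 8 with 1 array left out (0 without 24 h replicate 2 or control replicate 2, 8 without 24 h replicate 3). It was 5 at 48 h and 4 for 48 h against 24 h with series-table values, where leaving out 1 array gave 6 to 15 (14 without 24 h replicate 1, 15 without 48 h replicate 3), and 7 to 11 at 48 h against control. For the average it was 10 without further normalisation, 10 without the replicate 1 arrays and 4 to 7 with 1 array left out.

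With the labels of the series table, whose columns hold other groups' files, camera's direction turned for most lists, with these median log2 changes. At 24 h they were 0.206 (cardiac), -0.0864 (adipocyte) and -0.00922 (respiratory chain). At 48 h they were 0.265 (B cell), -0.047 (erythroid), -0.206 (matrix), -0.173 (type I interferon), -0.03 (interferon gamma), -0.188 (cell cycle), -0.094 (immediate early) and -0.0943 (glucocorticoid). For 48 h against 24 h they were -0.0756 (niche), -0.0243 (vascular), -0.0779 (matrix), -0.0185 (type I interferon), 0.000721 (cell cycle), 0.0377 (lipid) and 0.0425 (xenobiotic). For the average they were 0.27 (B cell), 0.0603 (cardiac), -0.045 (interferon gamma), -0.169 (cell cycle), -0.127 (immediate early) and -0.123 (glucocorticoid). The cell cycle median between the times stayed just above 0. Camera's direction was kept, with no call, by lipid genes at 24 h (median -0.0151, adjusted p = 0.984), cardiac genes at 48 h (-0.0373, 0.776) and, for 48 h against 24 h, B cell (-0.0314, 0.953) and immediate early genes (-0.0136, 0.888). The exchanged columns account for these medians and for the series-table counts. They belong to other comparisons of the same files and are not an effect of processing on the named comparison. Without the replicate 1 arrays the average cell cycle median was -0.0069 and the type I interferon median at 48 h -0.00328. With 1 array left out, medians ran from -0.392 to 0.114 for cardiac genes at 48 h (0.114 without 48 h replicate 3), from -0.0094 to 0.158 for erythroid genes at 48 h (-0.0094 without 48 h replicate 1), from -0.00624 to 0.248 for niche genes at 48 h against 24 h (-0.00624 without 48 h replicate 1) and from -0.00253 to 0.118 for cell cycle genes in the average (-0.00253 without control replicate 1). The cause of these was not tested. For cardiac genes the list mean at 48 h lay below control in each pair: 9.47 against 9.50, 9.44 against 9.47 and 8.47 against 9.03. Their turn to 0.114 came in a fit that left control replicate 3, the lowest control, unpaired. As the fits without 1 array had no replicate block, differences between replicate numbers enter them. Heat shock genes, higher in replicate 1, passed camera's preset correlation as higher at 24 h without control replicate 1 (median 0.241, adjusted p = 4.07e-05). Of the values of named genes, 31 of 1584 changed sign in the 9 fits without 1 array, 160 of 176 with series-table values and 10 of 1695 under the other 10 alternatives, and 0 passed the threshold.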

Other observations

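The contrasts between replicate numbers, the gene list tests on them and the test of 3-prime to 5-prime ratios were chosen after the arrays had been seen to group by number. Within groups, the replicate 1 arrays differed from those of replicates 2 and 3 in clock genes and heat shock genes, whether the lungs came from control or exosome-treated mice. By limma 2204 of 15886 probe sets passed (1066 higher and 1138 lower in replicate 1, with 4989 at an unadjusted p under 0.05), while 0 passed for replicate 2 (2771 unadjusted) and 0 for replicate 3 (1814 unadjusted) against the other numbers. Of 14 clock genes, 11 were lower and 2 higher past the threshold (median log2 -1.02, camera adjusted p = 1.61e-06, and adjusted p = 0.32 with an estimated correlation). Dbp, an output gene of the clock, was 4.67-fold lower in replicate 1 (log2 -2.22 ± 0.15 SE, limma adjusted p = 0.00054), and the feedback repressors Per3, Per1 and Per2 were 4.04-fold, 3.35-fold and 2.91-fold lower. Arntl, which encodes the activator that drives them, was 5.47-fold higher (log2 2.45 ± 0.15 SE, adjusted p = 0.00034).

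Heat shock genes were higher in replicate 1, with 10 of 18 past the threshold (median 0.463, camera adjusted p = 2.88e-09, and adjusted p = 0.32 with an estimated correlation), led by the inducible chaperone genes Hspa1b at 4.17-fold, Hspa1a at 2.99-fold and Hsph1 at 2.42-fold. Cirbp, which cells raise on cooling, was 2-fold lower. Platelet and megakaryocyte genes were higher on average, with 2 of 10 past the threshold (median 0.716, camera adjusted p = 0.000382, and adjusted p = 0.715 with an estimated correlation): the ADP receptor gene P2ry12 at 1.96-fold and the chemokine gene Ppbp at 1.87-fold. In control lungs replicate 1 did not stand apart in this list, with means of 8.33, 8.37 and 7.74 in replicates 1, 2 and 3. Cardiac muscle genes were higher by a median of 0.449 (adjusted p = 0.00228, and adjusted p = 0.731 with an estimated correlation), with 1 gene past the threshold. Replicate 1 hardly differed from replicate 2 in this list in control lungs (9.5 and 9.47) and at 48 h (9.47 and 9.44). The largest single difference was in Spon2, a matrix protein gene, at 5.84-fold higher. The skeletal muscle list averaged 9.34 on the log2 scale in 24 h replicate 1 and 6.51 to 7.49 on the other 8 arrays, and the neutrophil list 9.89 in 48 h replicate 1 and 8.52 to 9.07 on the others.

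A different time of day of tissue collection for replicate 1 is a candidate explanation for the opposite shifts of Arntl and the Per genes. Of 7 further clock genes named with a direction before their values were seen, 3 were detected and 2 went as predicted (Clock higher at 1.57-fold and Nr1d1 lower at 2.01-fold, but Cry1 at -0.04 on the log2 scale), an exact one-sided sign test p of 0.5, where 3 genes allow no less than 0.125. That test cannot decide. RNA integrity or labelling was examined through 3-prime to 5-prime ratios, of which 1 of 2 separated the replicate 1 arrays: Actb at 1.16 to 1.22 against 1.24 to 1.38, with Gapdh at 0.816 to 0.908 against 0.74 to 0.956. The signal of an 18S ribosomal RNA probe set, which was not part of that test, also separated them, at 8804 to 10068.7 units against 840.5 to 5077.9. The evidence leaves both open, and no collection time is given in the sources used here.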
